A study of Mus musculus with 59 samples.

How the data were processed

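Bulk RNA-seq of mouse tissue and cultured cells was taken from 59 libraries. Of these, 23 came from somatosensory cortex of Pten+/- and wild-type mice, by sex, at postnatal day 30 or 42 (P30 or P42). The other 36 came from cultured neural progenitors, cortical astrocytes and cortical neurons, each as a Pten+/- series with wild types and a Nes-KO series with controls, at 3 libraries per group. Progenitors were from embryonic day 12.5 and neurons from embryonic day 15.5, kept for 14 days in vitro. Astrocytes were taken at postnatal day 2 in the Pten+/- series and at postnatal day 0 in the Nes-KO series. The labels do not spell out the abbreviation Nes-KO, and it is used here as they give it.

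The deposited tables hold 1 signal value per gene and library, which the authors made as read counts per gene divided by 1 size factor per library, in the manner of DESeq2. The submitters name the mm10 build, HISAT2, featureCounts and DESeq2 and give no versions. The deposited tables also carry the authors' own log2 fold change, p value and adjusted p value for each gene (p_value columns). The mean of each gene over its libraries was checked against the deposited base mean and equalled it in every table. Every value above 0 was a whole multiple of the smallest step of its column (100% of values, tolerance 0.0001), so whole reads were recovered by division. In 24 of 105 columns the step lay so close to 1 that rounding alone would give a similar pattern. Those values were unrounded as well, and were treated like the rest. Genes with fewer than 3 reads over a table had been left out by the authors. Of 11 tables, 7 were used for values. The other 4 hold subsets of the cortex libraries, and their recovered reads did not differ from the full cortex table at any value (0 differing). They served only for the counts of the authors' calls.

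Recovered reads per library came to between 38.8 and 57.5 M (M for mega) in the cortex. In the Pten+/- series they came to 15.1 to 16.0 M in progenitors, 18.2 to 18.7 M in astrocytes and 18.5 to 18.9 M in neurons. In the Nes-KO series they came to 17.3 to 17.7, 16.5 to 17.2 and 18.8 to 26.3 M in the same order. At such depth a gene with 100 reads has a counting error of about 10%. Values are given as size-factor-normalised counts with the SD over libraries. Where a group holds a count of 0 in every library, up to 3 reads per library remain possible, and no fold is given.

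Gene names came from the tables and, where these had none, from the GENCODE M21 annotation of GRCm38, which is the same assembly as mm10. Sex was checked from Xist and 4 Y genes (Ddx3y, Eif2s3y, Kdm5d and Uty). No 2 libraries were duplicates of each other. Ribosomal protein genes and MHC class I genes have near-identical copies elsewhere in the genome, so the share of their reads that came from each copy is uncertain. Gene-level counts of Pten cannot show which exons were deleted.

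Since the tables hold normalised values, the main test was limma (lmFit, then eBayes with trend and robust) on log2(value + 1), after leaving out genes with a mean under 10. It served 15 comparisons, and p values were adjusted by Benjamini and Hochberg over the tested genes with a threshold of 0.05. All 23 cortex libraries went into 1 fit of 8 group means (age, sex and genotype). From it came the mean of the 4 within-stratum genotype differences, each stratum alone, the age and sex interactions, and the age and sex contrasts within wild types. Each culture table of 6 libraries was fitted alone. For 3 further comparisons, the Nes-KO effect minus the Pten+/- effect in each cell type, edgeR (quasi-likelihood, TMM, filterByExpr) was run on the recovered reads of both tables in 12-library fits. These had been planned for tables of counts only, and were run because the reads could be recovered. In them, series and sequencer model differ together with the mouse model, read length differs too in progenitors, and age differs in astrocytes. The Nes-KO and control astrocytes also differ in sex. All p values below are from limma unless edgeR is named.

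Groups of genes were tested with 33 fixed lists, written down before the data were examined. Of these, 32 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and the list of sex genes served as a check. For each list the count of members past the threshold over all genes is given, and the count when p values were adjusted over the list alone. The same test with a correlation estimated from the data, and the self-contained test fry, served as alternatives. Of 188 list results past the threshold at the preset correlation, 5 held with an estimated correlation. They were the microglia and SREBP1 lists in the cortex mean, the microglia list in P30 females, the immediate early genes in Pten+/- neurons, and the pan-neuronal list in the difference between models in progenitors. Sharing of called genes between comparisons was tested with a one-sided Fisher exact test per direction, adjusted over the pairs.

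Genes are named by a rule fixed before the data were examined. Pten and Nes are named everywhere. The 6 genes with the largest rise and the 6 with the largest fall are named if past the threshold, with a mean of at least 20 and no overlap between arms (in the cortex mean, the same sign in all 4 strata), predicted genes excluded. For up to 8 lists per comparison that pass camera or hold at least 2 members past the threshold, up to 4 members are named by p. The 6 genes called with the same sign in at least 2 of 3 cell types are named by their largest p. With 3 against 3 libraries, chance alone separates the arms in 10% of genes. Genes outside the rule are marked as chosen after their values were seen.

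The limma and edgeR fits were tested on simulated data, with 200 genes of the real tables changed by 1.5-fold or 2-fold. In the cortex mean 96% and 100% of these were recovered. In P42 females it was 77% and 86%, in Pten+/- progenitors 68% and 94%, in Nes-KO astrocytes 3% and 57%, and in the difference between models in progenitors 37% and 75%. Unchanged genes made up 6.67%, 5.23%, 12.0%, 7.69% and 3.45% of the calls in the same order.

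The alternatives planned before the data were examined were another pseudocount (0.25 or 5), no filter, a minimum absolute log2 fold change of 0.5, the replicate number of the labels as a block, a fit of each cortex stratum alone, an additive model, and leaving out each library in turn. For the joint fits they were DESeq2, size factors in place of TMM, and other filters. Chosen after seeing the data were edgeR and DESeq2 on the recovered reads, TMM scaling of the values, the Xist level as a covariate, leaving out P30 males, and limma on both tables of a cell type together. Whether replicate numbers pair libraries was decided by the correlation of residuals, with 0.1 required of every pair. No system met it (lowest values from -0.269 to 0.0839), so the numbers were not used in the main fits. Group labels were also exchanged, as all 10 splits of 3 against 3 libraries, 100 drawn splits in the cortex, and 40 in the joint fits. The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the main fits.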

Results

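RNA was measured in somatosensory cortex of Pten+/- and wild-type mice and in 3 kinds of cultured brain cells. The cortex series held 11 Pten+/- and 12 wild-type libraries. Each of the 8 groups by age, sex and genotype had 3 libraries, except the P30 Pten+/- males with 2. Neural progenitors, cortical astrocytes and cortical neurons each gave 3 Pten+/- and 3 wild-type libraries, and, in a separate series, 3 Nes-KO and 3 control libraries. Recovered reads per library lay between 38.8 and 57.5 M in the cortex and between 15.1 and 26.3 M in the cultures, where M stands for mega. Values are normalised counts with the SD over libraries, and fold changes are on the log2 scale with their standard error (SE). Unless edgeR is named, p values come from limma.

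The first question was how far Pten, the phosphatase that opposes PI3K signalling, was lowered in each system. Pten (ENSMUSG00000013663, GRCm38, chromosome 19, 32757497 to 32826160) was at 72.4% of wild type in P30 females, 78.2% in P30 males, 74.1% in P42 females and 75.4% in P42 males. In the Pten+/- cultures it was at 75.4% in progenitors, 72.7% in astrocytes and 81.0% in neurons. In the Nes-KO cultures it was at 62.6%, 43.5% and 75.2% of control in the same order. The 43.5% in astrocytes depends on 1 of 3 control libraries with a low Pten of 1764, against 3787 and 3609, whose state the labels do not settle. It fell over all cortex libraries, from 9123 (SD 643, n = 12) to 6835 (SD 357, n = 11), by a log2 fold change of -0.41 (SE 0.0396, adjusted p = 2.72e-07). Nestin (Nes, ENSMUSG00000004891, chromosome 3, 87971078 to 87980451), an intermediate filament of progenitors, was not called lower in any comparison. In Nes-KO progenitors it stood lower without passing, at -0.26 (SE 0.107, adjusted p = 0.159). Nes was called higher in Nes-KO neurons alone, from 136 (SD 13.7) to 330 (SD 59.8).

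**Figure D1:**
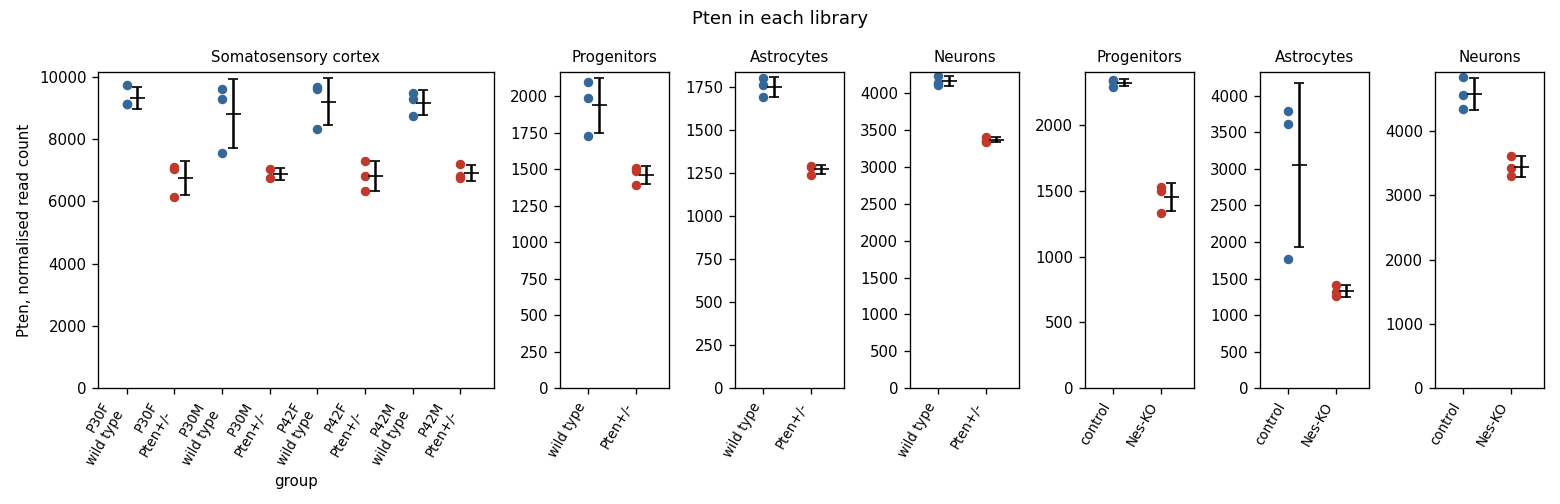
Normalised Pten count of each library (y axis, from 0) in the cortex and the 6 culture tables, blue for wild type or control and red for Pten+/- or Nes-KO, with the group mean and SD in black beside the points. Pten lay at between 43.5% and 81.0% of the control mean in every system.

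Cortex of Pten+/- mice was compared with wild type, as the mean of the 4 differences within age and sex, to ask what a lower Pten dose does to the young adult cortex. Of 18392 genes tested, 116 changed, 104 of them higher and 12 lower. Of the genes that rose, 9 were on the microglia list, 3 on the myelin list, 1 on the oligodendrocyte precursor list and 2 on the endothelial and pericyte list. The complement subunit C1qc rose from 2026 (SD 161, n = 12) to 2508 (SD 134, n = 11), a log2 fold change of 0.30 (SE 0.0411, adjusted p = 0.000269). The lysosomal protein Laptm5 (0.28, SE 0.0396), the receptor for the colony-stimulating factor Csf1r (0.22, SE 0.0323) and C1qb (0.25, SE 0.0430) rose with it, as did Crybb1 (0.50, SE 0.0760, adjusted p = 0.000548). Of 19 microglia and macrophage markers, 9 rose and none fell, 15 rose when adjusted over the list alone, and the median was 0.23. This list passed camera (adjusted p = 1.01e-23) and held with an adjusted p = 0.00502 with an estimated correlation.

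Fewer genes of the oligodendrocyte lineage passed the threshold. The connexins Gjb1 (0.44, SE 0.0997, adjusted p = 0.0443) and Gjc2 (0.41, SE 0.0835, adjusted p = 0.0276), which couple oligodendrocytes to astrocytes, rose, as did the myelin glycoprotein Mag (0.38, SE 0.0766) and the protease Klk6 (0.44, SE 0.104). The receptor Gpr17, a marker of newly formed oligodendrocytes, rose from 3699 (SD 736) to 4403 (SD 927). Cnp (0.34, SE 0.0767, adjusted p = 0.0559) and Olig1 (0.24, SE 0.0569, adjusted p = 0.0521) did not pass. All 21 mature oligodendrocyte and myelin markers were above 0, 3 of them past the threshold over all genes and 20 adjusted over the list alone. Their median was 0.34 (camera adjusted p = 1.31e-23, adjusted p = 0.082 with an estimated correlation). Of 13 precursor and newly formed oligodendrocyte markers, 1 rose, and 10 did so adjusted over the list alone, with a median of 0.19 (adjusted p = 6.64e-11, adjusted p = 0.0726 with an estimated correlation).

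**Figure D2:**
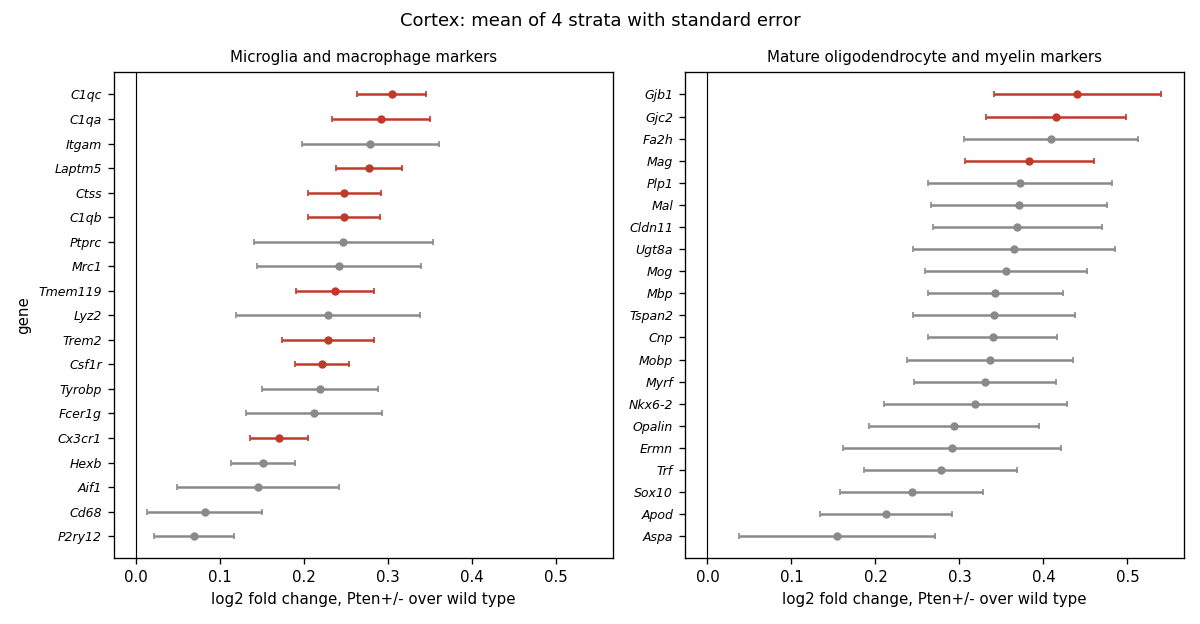
Log2 fold change of Pten+/- over wild-type cortex with SE bars for 19 microglia markers and 21 myelin markers, red where the adjusted p was under 0.05 and grey otherwise. All members of both lists lie above 0.

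Some lipid, vessel and immune genes rose as well. The desaturases Scd1 (0.18, SE 0.0371, adjusted p = 0.0189) and Scd2 (0.15, SE 0.0313, adjusted p = 0.019) rose. They belong to 15 SREBP1 fatty acid synthesis genes, of which 2 rose over all genes and 11 adjusted over the list alone (median 0.09, camera adjusted p = 4.84e-09, adjusted p = 0.0155 with an estimated correlation). Of 25 SREBP2 cholesterol synthesis genes none passed over all genes and 2 rose adjusted over the list alone (median 0.08, adjusted p = 2.43e-06, adjusted p = 0.134 with an estimated correlation). Kcnj8, the channel subunit that marks pericytes, rose from 121 (SD 29.6) to 183 (SD 32.8), or by 0.60 (SE 0.106, adjusted p = 0.0044), and the pericyte regulator Rgs5 by 0.16 (SE 0.0384). These were the 2 of 17 endothelial and pericyte markers that rose, 8 adjusted over the list alone (median 0.14, adjusted p = 7.3e-09, adjusted p = 0.0509 with an estimated correlation). B2m (0.15, SE 0.0303) and H2-K1 (0.25, SE 0.0571), of antigen presentation, were 2 of 21 interferon and MHC class I genes that rose, 6 adjusted over the list alone (median 0.17, adjusted p = 5.54e-08, adjusted p = 0.0573 with an estimated correlation). None of 18 astrocyte markers passed and 8 rose adjusted over the list alone (median 0.08, adjusted p = 5.35e-09, adjusted p = 0.082 with an estimated correlation). The ferric reductase Cybrd1 (0.70, SE 0.158) and the carbonyl reductase Cbr2 (0.70, SE 0.161, adjusted p = 0.0319) had the largest rises of all named genes.

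Few genes fell apart from Pten. Cntnap3, a neuronal adhesion gene, fell from 292 (SD 40.4) to 215 (SD 26.5), by -0.43 (SE 0.0759, adjusted p = 0.0044). The deep-layer transcription factor Foxp2 (-0.28, SE 0.0627, adjusted p = 0.0304), the Wnt enhancer Rspo3 (-0.31, SE 0.0697), the protocadherin Pcdhga3 (-0.34, SE 0.0790) and Bex4 (-0.33, SE 0.0703) fell as well. Foxp2 was the 1 of 16 glutamatergic and cortical layer markers past the threshold (median -0.02, adjusted p = 0.103). The 12 striatal markers had a median of -0.12, with 1 lower adjusted over the list alone (adjusted p = 0.00363, adjusted p = 0.256 with an estimated correlation).

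Other lists passed camera with small medians and lost the call once the correlation was estimated. They were glycolysis and hypoxia response (1 of 27 rose, median 0.03, adjusted p = 0.00328, adjusted p = 0.246 with an estimated correlation), neural progenitor markers (median 0.06, adjusted p = 0.00301, adjusted p = 0.102 with an estimated correlation) and reactive astrocyte genes (median 0.05, adjusted p = 0.0247, adjusted p = 0.191 with an estimated correlation). The ATF4 and amino acid response had a median of 0.02 (adjusted p = 0.0285, adjusted p = 0.102 with an estimated correlation), cell cycle and DNA replication 0.12 (adjusted p = 0.0415, adjusted p = 0.246 with an estimated correlation), and Wnt, Notch and Hedgehog targets 0.07 (adjusted p = 0.0495, adjusted p = 0.246 with an estimated correlation). Autism risk genes (median -0.02, adjusted p = 0.0304, adjusted p = 0.676 with an estimated correlation) and cytosolic ribosomal proteins (median -0.02, adjusted p = 0.0415, adjusted p = 0.821 with an estimated correlation) lay slightly below 0.

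The remaining lists did not pass in the cortex. For the PI3K-AKT-mTOR pathway the adjusted p was 0.319, and Pten alone of 30 members fell. Nuclear-encoded respiratory chain genes (adjusted p = 0.0966), mitochondrially encoded transcripts (0.81), dorsal (0.218) and ventral (0.674) patterning genes, synaptic genes (0.0808) and red blood cell transcripts (0.207) held no called member. Pan-neuronal markers held 2 that rose (0.135) and the fibroblast and matrix list 1 (0.156). In 5 lists the median, the mean and the test did not share a sign. FOXO targets had a median of -0.01 and a mean of 0.01 (tested up, 0.81), interneuron markers 0.01 and -0.003 (down, 0.833), immediate early genes 0.01 and -0.01 (down, 0.705), choroid plexus and ependymal markers 0.004 and -0.12 (up, 0.666), and clock genes -0.01 and 0.01 (down, 0.563). The authors' deposited values call 361 genes in this comparison, 308 higher and 53 lower. Leaving out 1 library gave between 27 and 175 called genes, and a minimum absolute log2 fold change of 0.5 left 5.

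Each stratum of age and sex was then taken alone, to see whether the cortex effect is carried by 1 age or sex. In P30 females 2 genes changed. Pten fell (-0.47, SE 0.0767, adjusted p = 0.0161), and the adhesion receptor Adgrg1, expressed in glia, rose from 2351 (SD 103, n = 3) to 3197 (SD 183, n = 3), by 0.44 (SE 0.0748, adjusted p = 0.0161). No gene passed in the other strata. There Pten stood at -0.35 (SE 0.0858, adjusted p = 0.449) in P30 males, -0.43 (SE 0.0767, adjusted p = 0.0724) in P42 females and -0.41 (SE 0.0767, adjusted p = 0.0867) in P42 males. The counts of 0 in P30 males, P42 females and P42 males are from limma, with 905, 1064 and 846 genes at unadjusted p under 0.05. With edgeR on the recovered reads the counts were 0, 1 and 0, and with DESeq2 0, 6 and 4. When each stratum was fitted with its own libraries alone, limma called 0, 0 and 29, and 4 in P30 females. The deposited values of the authors, which pool strata, call 174 genes in females, 28 in males, 12 at P30 and 155 at P42.

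The myelin and microglia lists had medians above 0 in all 4 strata, and whether their size was the same was tested only by the interactions. The myelin list had a median of 0.38 in P30 females (camera adjusted p = 1.17e-12, adjusted p = 0.219 with an estimated correlation), 0.15 in P30 males (0.00425, adjusted p = 0.723 with an estimated correlation), 0.38 in P42 females (1.14e-12, adjusted p = 0.514 with an estimated correlation) and 0.44 in P42 males (5.39e-16, adjusted p = 0.279 with an estimated correlation). The microglia list had a median of 0.29 in P30 females, where 11 of 19 members rose adjusted over the list alone (6.27e-16, adjusted p = 0.0305 with an estimated correlation). It was 0.24 in P30 males (6.48e-09, adjusted p = 0.14 with an estimated correlation), 0.23 in P42 females (3.1e-10, adjusted p = 0.178 with an estimated correlation) and 0.18 in P42 males (4.75e-09, adjusted p = 0.267 with an estimated correlation). Striatal markers stood lower in P30 males, with a median of -0.50 and 7 of 12 lower adjusted over the list alone (5.6e-10, adjusted p = 0.117 with an estimated correlation). Gpr6 (-1.46, SE 0.333, adjusted p = 0.339) and Rgs9 (-0.73, SE 0.231) did not pass over all genes. At unadjusted p under 0.01, P30 and P42 females shared 38 higher genes where 1.57 would be shared by independent lists (adjusted p = 8.02e-41). P42 females and males shared 15 against 0.902 (adjusted p = 9.57e-14). The strata share 1 estimate of the spread per gene and the test takes genes as independent, so these p values may be too small. Over all genes the fold changes correlated at 0.0855 and 0.0600 in these pairs. Between P30 and P42 males the correlation was 0.0416, and between P30 females and males 0.0179.

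Whether the genotype effect differs by age or by sex was tested as an interaction. No gene passed in either test by limma. Unadjusted p was under 0.05 for 488 genes by age and 933 by sex. edgeR gave 0 and 0, and DESeq2 0 and 1. By age, striatal markers (median 0.18, adjusted p = 0.00109) and fibroblast genes (-0.14, adjusted p = 0.0276) passed camera (both adjusted p = 0.975 with an estimated correlation). By sex, with females minus males, SREBP2 genes (0.08), immediate early genes (-0.29) and striatal markers (0.23) passed at an adjusted p = 0.00652 (each adjusted p = 0.838 with an estimated correlation). So did ribosomal protein genes (0.05, adjusted p = 0.00652, adjusted p = 0.895 with an estimated correlation) and mitochondrially encoded transcripts (-0.09, adjusted p = 0.0259, adjusted p = 0.838 with an estimated correlation). Both interactions also contain the wild-type difference by age or sex, with its sign turned.

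Wild-type cortex at P42 was compared with P30, with 6 libraries each, as context for the genotype effect. Age and litter or batch cannot be told apart in this contrast. Of 141 genes that changed, 72 were higher and 69 lower at P42. Marcksl1, a growth-associated actin regulator, fell from 3415 (SD 276) to 2334 (SD 235), by -0.55 (SE 0.0589, adjusted p = 1.84e-06). Gpr17 (-0.50, SE 0.0674, adjusted p = 0.000145), the oligodendrocyte factor Zfp488 (-0.62, SE 0.130), the kinesin Kif19a (-0.49, SE 0.106), Rxfp2 (-0.88, SE 0.182) and the imprinted Mkrn3 (-0.83, SE 0.152) fell too. Mdfic2 rose from 116 (SD 32.2) to 282 (SD 63.5), by 1.29 (SE 0.178, adjusted p = 0.000145). Among the other large rises were Xdh (1.18, SE 0.234), Espn (0.70, SE 0.110), Mybl1 (0.67, SE 0.145), the RNA sensor Ddx58 (0.62, SE 0.122) and Plk5 (0.55, SE 0.0962). The sex genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty did not change with age (lowest adjusted p = 0.172).

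Lists were also tested with age. SREBP2 cholesterol genes had a median of -0.16, with 2 of 25 lower over all genes, and 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.84e-09, adjusted p = 0.451 with an estimated correlation). Myelin markers had a median of -0.29, with 10 of 21 lower adjusted over the list alone (adjusted p = 1.66e-10, adjusted p = 0.595 with an estimated correlation). Precursor markers stood at -0.15 (1 of 13 fell, adjusted p = 0.000252, adjusted p = 0.595 with an estimated correlation), and nuclear-encoded respiratory chain genes at -0.05 (3 of 60 fell, adjusted p = 1.44e-06, adjusted p = 0.985 with an estimated correlation). Striatal markers stood at -0.30 (1 of 12 fell, adjusted p = 5.72e-05, adjusted p = 0.586 with an estimated correlation) and the 5 red blood cell transcripts at -0.93 (adjusted p = 0.000578, adjusted p = 0.595 with an estimated correlation). Interferon genes stood at 0.15, with 4 of 21 higher adjusted over the list alone (adjusted p = 0.00892, adjusted p = 0.595 with an estimated correlation). Leaving out 1 library gave between 51 and 139 called genes.

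Wild-type females were compared with males at both ages, as a check of the labels and to list sex differences. Of 17 genes that changed, 8 were higher and 9 lower in females, and 9 lay on X or Y. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254) stood at 17026 (SD 762, n = 6) in females and 1.68 (SD 1.91, n = 6) in males. Of the Y genes, Ddx3y stood at 2377 (SD 226), Eif2s3y at 1749 (SD 70.9), Kdm5d at 1111 (SD 141) and Uty at 536 (SD 58.8) in males. All 4 were 0 in females, where a count of 0 allows up to 3 reads per library. On the X chromosome Eif2s3x (0.52, SE 0.0491, adjusted p = 3.58e-08), Kdm5c (0.38, SE 0.0486) and Ddx3x (0.27, SE 0.0463) were higher in females. Off the sex chromosomes the adhesion gene Sdk2 (0.42, SE 0.0759, adjusted p = 0.00773) and the pentraxin Nptx1 (0.27, SE 0.0494) were higher in females. Sertm1 (-0.33, SE 0.0627) and Rasl11b (-0.28, SE 0.0536, adjusted p = 0.0173) were lower. Clock genes had a median of 0.17, with 6 of 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.56e-05, adjusted p = 0.685 with an estimated correlation). Ribosomal protein genes stood at -0.08, with 76 of 77 below 0 (adjusted p = 2.45e-10, adjusted p = 0.795 with an estimated correlation). Without 1 P42 wild-type female library the count was 26.

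In cultured progenitors, Pten+/- was compared with wild type to ask whether the embryonic precursors already respond to a lower dose. No gene passed by limma among 14411 tested. Unadjusted p was under 0.05 for 501 genes, and edgeR and DESeq2 on the recovered reads also called 0. The deposited values of the authors call none either (lowest adjusted p = 0.127). Pten stood at 1461 (SD 60.7, n = 3) against 1937 (SD 188, n = 3), at -0.40 (SE 0.0794, unadjusted p = 0.000567, adjusted p = 1). Nes stood at 0.09 (SE 0.120, adjusted p = 1). Clock genes had a median of -0.40 (camera adjusted p = 0.000223), with Nr1d2 at -0.49, Cry2 at -0.51 and Per3 at -0.40, none of them past the threshold (adjusted p = 1). Glycolysis and hypoxia genes (-0.31, adjusted p = 0.00693), SREBP2 genes (-0.09, adjusted p = 0.000408), ribosomal protein genes (-0.04, adjusted p = 0.00347), the ATF4 response (-0.14, adjusted p = 0.0229) and reactive astrocyte genes (0.26, adjusted p = 0.0205) also passed camera. Each of these lists, clock genes included, had an adjusted p = 0.889 with an estimated correlation. Without the first wild-type library, 290 genes were called.

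Pten+/- astrocytes were compared with wild type to ask how the lower dose acts in astrocyte cultures. Of 16127 genes, 51 changed, 27 higher and 24 lower. Elastin (Eln) rose from 433 (SD 26.0, n = 3) to 724 (SD 133, n = 3), by 0.73 (SE 0.111, adjusted p = 0.0198). Podn (0.58, SE 0.0905), the laminin receptor subunit Itga7 (0.51, SE 0.0741), fibronectin Fn1 (0.39, SE 0.0542, adjusted p = 0.00641) and Igfbp2 (0.31, SE 0.0561) rose. So did the adrenergic receptor Adra1d (0.61, SE 0.123), the transcription factor Cebpb (0.51, SE 0.105), the corepressor Hr (0.49, SE 0.0661) and the astrocyte filament Gfap (0.23, SE 0.0431, adjusted p = 0.0296). Pten fell from 1747 (SD 56.2) to 1270 (SD 26.8), by -0.46 (SE 0.0510, adjusted p = 0.000444). The sulfatase Sulf1 (-0.68, SE 0.0774, adjusted p = 0.000444), the organic anion carrier Slco1a4 (-0.49, SE 0.0501, adjusted p = 0.000264), Tox2 (-0.77, SE 0.107), the retinol-binding Rbp1 (-0.71, SE 0.121), Ccdc190 (-0.49, SE 0.0909) and Emp1 (-0.29, SE 0.0487) fell. Nes did not change (-0.01, SE 0.0488, adjusted p = 0.956).

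By groups, interferon and MHC class I genes in Pten+/- astrocytes had a median of 0.17, with none past the threshold over all genes and 7 of 20 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000961, adjusted p = 0.872 with an estimated correlation). The ATF4 response (1 of 23 rose, median 0.09, adjusted p = 0.0044), SREBP1 genes (median 0.04, adjusted p = 0.0363) and nuclear-encoded respiratory chain genes (median 0.07, adjusted p = 0.0048) passed camera too, each with an adjusted p = 0.872 with an estimated correlation. SREBP2 genes (0.08, adjusted p = 0.0048, adjusted p = 0.961 with an estimated correlation) and microglia markers (0.27, adjusted p = 0.0067, adjusted p = 0.982 with an estimated correlation) held no called member. Of 17 fibroblast and matrix genes, 2 rose, and 4 did adjusted over the list alone (adjusted p = 0.0603). The authors' deposited values call 105 genes, 60 higher and 45 lower. Leaving out 1 library gave between 4 and 151 called genes, and the Xist level as a covariate left 27.

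Pten+/- neurons at 14 days in vitro were compared with wild type to ask how the lower dose acts in mature neurons. All 32 genes that changed fell, and 14 of them are on the list of immediate early genes, which neurons switch on within minutes of activity. Fosb fell from 3498 (SD 260, n = 3) to 351 (SD 44.7, n = 3), by -3.32 (SE 0.0973, adjusted p = 4.77e-07). Arc, which trims synaptic receptors, fell from 1520 (SD 252) to 170 (SD 31.3), by -3.16 (SE 0.152), and Egr1 from 5396 (SD 391) to 1135 (SD 85.8), by -2.25 (SE 0.0720). Npas4 (-1.83, SE 0.0560), Junb (-1.73, SE 0.0654), Egr2 (-3.06, SE 0.180), Btg2 (-2.61, SE 0.108) and Ccn1 (-2.43, SE 0.0766) fell in step, with adjusted p values from 4.77e-07 to 3.84e-05. Of 18 immediate early genes, 14 fell over all genes and 16 adjusted over the list alone. Their median was -1.77 (camera adjusted p = 3.75e-42), and the call held with an adjusted p = 0.0146 with an estimated correlation.

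Pten itself fell from 4161 (SD 66.2) to 3370 (SD 36.9) in Pten+/- neurons, by -0.30 (SE 0.0437, adjusted p = 0.0329), while Nes did not change (0.53, SE 0.382, adjusted p = 0.814). Interneuron markers had a median of 0.28 (camera adjusted p = 0.024), glutamatergic and layer markers -0.18 (adjusted p = 0.0352), autism risk genes -0.05 (adjusted p = 0.024), ribosomal protein genes -0.03 (adjusted p = 0.024) and nuclear-encoded respiratory chain genes 0.07 (adjusted p = 0.00157). No member of these lists passed, and all had an adjusted p = 0.786 with an estimated correlation. Among layer markers, the deep-layer genes Etv1 (-0.66, SE 0.145, adjusted p = 0.267) and Tle4 (-0.78, SE 0.164) and the upper-layer gene Cux2 (0.33, SE 0.0742) did not pass. The authors' deposited values call 77 genes, 7 higher and 70 lower. All 3 Pten+/- cultures were Y-positive and 1 of 3 wild types was. With the Xist level as a covariate 20 genes were called, and leaving out 1 library gave between 20 and 55 (55 without wild type 2, 21 and 20 without Pten+/- 2 or 3).

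Nes-KO progenitors were compared with their controls to ask what the second model does in precursors. Of 15088 genes, 1859 changed, 1118 higher and 741 lower. Pten fell from 2324 (SD 27.0, n = 3) to 1456 (SD 108, n = 3), by -0.68 (SE 0.0623, adjusted p = 1.53e-05). Neuronal genes were among the largest rises. The synuclein Sncb rose by 2.85 (SE 0.344, adjusted p = 0.000177), the microtubule regulator Stmn2 by 2.61 (SE 0.448), the adhesion gene Cntn2 by 2.22 (SE 0.299), and the tubulin Tubb3 from 396 (SD 58.8) to 736 (SD 70.9). Eno2 (0.93, SE 0.154), Elavl3 (0.45, SE 0.0665), Shtn1 (2.24, SE 0.349), Gsg1l (2.14, SE 0.350) and the incretin receptor Gipr (2.71, SE 0.374) rose as well. Of 14 pan-neuronal markers 8 rose, 9 up and 1 down adjusted over the list alone (median 0.49, camera adjusted p = 0.000215, adjusted p = 0.211 with an estimated correlation). Synaptic genes held 9 that rose and 2 that fell of 37 (median 0.15, adjusted p = 0.00167, adjusted p = 0.357 with an estimated correlation).

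Metabolic genes were tested in Nes-KO progenitors as 4 lists. Of 27 glycolysis and hypoxia genes, 16 rose and 21 did adjusted over the list alone (median 0.62, camera adjusted p = 1.35e-14, adjusted p = 0.357 with an estimated correlation). The rate-limiting kinase subunit Pfkl rose from 2127 (SD 112) to 4234 (SD 362), by 0.99 (SE 0.0656, adjusted p = 1.01e-06), with Tpi1 (0.93, SE 0.0646), Pgam1 (0.74, SE 0.0632) and Aldoa (0.67, SE 0.0578). Of 15 SREBP1 genes 8 rose, 12 adjusted over the list alone, among them the acetyl-CoA ligase Acss2 (0.91, SE 0.0634), Thrsp (1.49, SE 0.128), Scd1 (0.51, SE 0.0719) and Scd2 (0.46, SE 0.0607), with a median of 0.28 (adjusted p = 9.05e-07, adjusted p = 0.281 with an estimated correlation). SREBP2 genes had 6 of 25 that rose (median 0.16, adjusted p = 0.00245, adjusted p = 0.565 with an estimated correlation). Of 24 ATF4 targets 12 rose, 13 adjusted over the list alone, such as Asns (0.52, SE 0.0680), Sesn2 (0.49, SE 0.0699), Slc7a5 (0.35, SE 0.0572) and Chac1 (0.96, SE 0.165). Their median was 0.34 (adjusted p = 7.11e-07, adjusted p = 0.211 with an estimated correlation).

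Most ribosomal protein genes and a smaller share of replication genes fell in Nes-KO progenitors. Of 77 cytosolic ribosomal protein genes, 60 fell and 73 did adjusted over the list alone, by small steps (median -0.24, camera adjusted p = 7.21e-21, adjusted p = 0.386 with an estimated correlation). Examples are Rpl21 (-0.31, SE 0.0534), Rps21 (-0.32, SE 0.0548), Rps12 (-0.32, SE 0.0568) and Rps4x (-0.30, SE 0.0542). Of 33 cell cycle genes 11 fell, 18 adjusted over the list alone, including Mcm7 (-0.39, SE 0.0722), Tyms (-0.39, SE 0.0821), Ccne2 (-0.42, SE 0.0995) and Kif11 (-0.23, SE 0.0548), with a median of -0.17 (adjusted p = 5.91e-06, adjusted p = 0.503 with an estimated correlation). Of 12 mitochondrially encoded transcripts 3 fell, 5 adjusted over the list alone, ND1 by -0.32 (SE 0.0520) first (median -0.23, adjusted p = 0.00137, adjusted p = 0.357 with an estimated correlation). The carbonic anhydrase Car3 fell from 1860 (SD 89.4) to 700 (SD 43.9), by -1.41 (SE 0.0672, adjusted p = 2.93e-08). Mylk (-1.82, SE 0.348), Dhh (-1.41, SE 0.216), Pou3f1 (-1.27, SE 0.266), Thbs1 (-1.26, SE 0.236) and Prdm1 (-1.09, adjusted p = 0.0287) followed.

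Interferon and MHC class I genes of Nes-KO progenitors held 5 that rose and 1 that fell of 15 (median 0.34, camera adjusted p = 0.000285, adjusted p = 0.211 with an estimated correlation), led by H2-K1 (0.88, SE 0.0753) and H2-D1 (0.64, SE 0.0696), with Gbp3 down (-0.81, SE 0.166). Of 14 reactive astrocyte genes 4 rose and 1 fell (median 0.53, adjusted p = 0.00386, adjusted p = 0.211 with an estimated correlation). Interneuron markers (0.63, adjusted p = 0.0138) and dorsal patterning genes (3 of 8 rose, 0.56, adjusted p = 0.0482) also passed, both with an adjusted p = 0.386 with an estimated correlation. Nes stood at -0.26 (SE 0.107, adjusted p = 0.159). The authors' deposited values call 1792 genes, 1095 higher and 697 lower. Leaving out 1 library gave between 690 and 2265 called genes.

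Nes-KO astrocyte cultures were compared with their controls to ask what the model does in glia. Of 16017 genes, 6585 changed, 3523 higher and 3062 lower. Sex split the arms as well. Xist stood at 11.7 (SD 2.69, n = 3) in Nes-KO and 15052 (SD 2393, n = 3) in control cultures. The Y genes Ddx3y at 1214 (SD 84.1), Eif2s3y at 1094 (SD 121) and Uty at 547 (SD 44.5) were found in Nes-KO alone, and a count of 0 allows up to 3 reads per library in the controls. Pten fell from 3053 (SD 1120) to 1328 (SD 77.6), by -1.12 (SE 0.270, adjusted p = 0.0136), or by -1.48 (SE 0.0832) without the control library with low Pten. Without the second control it did not pass (-0.96, SE 0.294, adjusted p = 0.053, the highest of its alternatives, which ran from 7.47e-06). Nes stood at 0.04 (SE 0.107, adjusted p = 0.794).

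Cell cycle genes rose in nearly every case in Nes-KO astrocytes, 30 of 33 with 1 lower, by a median of 2.67 (camera adjusted p = 2.4e-09, adjusted p = 0.619 with an estimated correlation). The proliferation marker Mki67 rose from 287 (SD 48.1) to 3552 (SD 2021), by 3.49 (SE 0.358, adjusted p = 0.000449), with Plk1 (4.01, SE 0.417), Aurkb (3.20, SE 0.325) and Kif11 (3.14, SE 0.321). Oligodendrocyte precursors' receptor Pdgfra rose from 40.3 (SD 17.0) to 2155 (SD 483), by 5.78 (SE 0.343, adjusted p = 7.53e-05). Lhfpl3 (4.57, SE 0.413), Gpr17 (4.75, SE 0.431) and Mbp (2.51, SE 0.288) rose too. Cldn11 stood at 203 (SD 75.9) against 2.02 (SD 3.49), Sox10 at 372 (SD 207) against 0.671 (SD 0.581) and Bcas1 at 426 (SD 214) against 1.01 (SD 1.01). Of 13 precursor markers 9 rose and 1 fell (median 2.53, adjusted p = 0.000748, adjusted p = 0.456 with an estimated correlation). Of 14 mature markers 9 rose, 10 adjusted over the list alone (median 1.92, adjusted p = 0.00108, adjusted p = 0.385 with an estimated correlation). Of 19 microglia markers 18 rose (median 1.94, adjusted p = 1.36e-05, adjusted p = 0.642 with an estimated correlation), such as Tmem119 (3.01, SE 0.389), P2ry12 (2.58, SE 0.449), Mrc1 (4.42, SE 0.847) and Cx3cr1 (2.07, SE 0.404). Fam216b stood at 677 (SD 228) against 2.69 (SD 4.65), and Mcidas, a regulator of multiciliated cells, at 473 (SD 254) against 0.671 (SD 0.581).

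Astrocyte markers rose as well in the Nes-KO cultures, 11 of 17 with 1 lower (median 1.24, camera adjusted p = 0.00108, adjusted p = 0.642 with an estimated correlation). The water channel Aqp4 rose from 2422 (SD 1919) to 20514 (SD 935), by 3.36 (SE 0.448, adjusted p = 0.00119), and Gja1 (1.90, SE 0.0991), S100b (2.75, SE 0.210) and Slc6a11 (2.92, SE 0.402) with it. FOXO targets fell, 16 of 27 with 1 higher (median -0.63, adjusted p = 0.000176, adjusted p = 0.619 with an estimated correlation). Among them were the insulin receptor Insr (-1.82, SE 0.101), Igf1r (-2.82, SE 0.173), Irs2 (-1.54, SE 0.110) and Gadd45a (-3.22, SE 0.183), all genes that FOXO factors activate when PI3K is low. Immediate early genes fell, 9 of 16 with 1 higher (median -1.05, adjusted p = 0.00191, adjusted p = 0.619 with an estimated correlation). Ribosomal protein genes rose, 40 of 77, with 54 higher and 1 lower adjusted over the list alone (median 0.26, adjusted p = 8.04e-07, adjusted p = 0.456 with an estimated correlation), Rps2 (0.70, SE 0.0878) and Rpl7a (0.53, SE 0.0815) first. Among the largest falls were the chemokine Cxcl12, from 1064 (SD 505) to 13.7 (SD 2.01), Htr5b (-6.01, SE 0.788) and Fibin (-6.00, SE 0.473). Esm1 stood at 1.96 (SD 0.988) against 236 (SD 169) and Tmigd1 at 0.328 (SD 0.569) against 79.6 (SD 28.1).

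Further lists in Nes-KO astrocytes were nuclear-encoded respiratory chain genes (24 of 60 rose, median 0.23, adjusted p = 0.000337, adjusted p = 0.642 with an estimated correlation) and interneuron markers (8 of 10 rose, median 1.48, adjusted p = 0.00246, adjusted p = 0.385 with an estimated correlation). SREBP1 genes (7 of 14 rose, median 0.42, adjusted p = 0.00661, adjusted p = 0.527 with an estimated correlation) and interferon genes (10 of 21 fell, median -0.58, adjusted p = 0.0453, adjusted p = 0.804 with an estimated correlation) followed. SREBP2 genes (median 0.01, mean -0.06) and glycolysis genes (median 0.02, mean -0.12) had medians and means of opposite sign and did not pass (both adjusted p = 0.932). The authors' deposited values call 6802 genes, 3712 higher and 3090 lower. Without the second control library the count was 4388.

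Nes-KO neurons were compared with their controls to ask what the model does after 14 days in vitro. Of 15142 genes, 6192 changed, 3103 higher and 3089 lower. Somatostatin (Sst), the peptide of 1 interneuron class, fell from 16113 (SD 1539, n = 3) to 1564 (SD 284, n = 3), by -3.38 (SE 0.132, adjusted p = 5e-06). Of 16 interneuron markers 11 fell and 1 rose (median -1.28, camera adjusted p = 0.00233, adjusted p = 0.503 with an estimated correlation), and the 1 that rose was the peptide Cck (1.94, SE 0.114). Of 13 ventral patterning genes 10 fell (median -1.40, adjusted p = 0.000275, adjusted p = 0.503 with an estimated correlation), among them Ascl1 (-2.55, SE 0.157), Lhx6 (-2.49, SE 0.134), Arx (-2.14, SE 0.137) and Dlx2 (-1.86, SE 0.208). Immediate early genes fell, 10 of 18 (median -0.94, adjusted p = 0.000333, adjusted p = 0.549 with an estimated correlation), such as Ier2 (-1.40, SE 0.246), Dusp1 (-1.28, SE 0.221), Ier5 (-0.74, SE 0.137) and Dusp6 (-0.38, SE 0.0901). Among the largest falls were Synpo2l (-4.54, SE 0.213), Pappa (-3.77, SE 0.265), Tcap (-3.63, SE 0.212), the Wnt inhibitor Wif1 (-3.57, adjusted p = 0.00458) and Arhgap36 (-3.54, SE 0.202). Pten fell from 4579 (SD 249) to 3445 (SD 161), by -0.41 (SE 0.0602, adjusted p = 0.000438), and Nes rose by 1.27 (SE 0.140, adjusted p = 7.74e-05).

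Sterol and fatty acid genes rose in Nes-KO neurons. Of 25 SREBP2 genes 22 rose and 1 fell (median 0.65, camera adjusted p = 3.32e-08, adjusted p = 0.485 with an estimated correlation), with Mvk (1.35, SE 0.0932), Nsdhl (1.23, SE 0.0846), Tm7sf2 (1.06, SE 0.0860) and Acat2 (0.84, SE 0.0719). Of 15 SREBP1 genes 11 rose and 1 fell (median 0.38, adjusted p = 9.41e-05, adjusted p = 0.485 with an estimated correlation). Scd1 rose from 553 (SD 52.9) to 2106 (SD 178), by 1.93 (SE 0.0847, adjusted p = 4.54e-07), with Me1 (1.18, SE 0.0760), Acly (1.01, SE 0.0831) and Scd2 (0.90, SE 0.0770). Genes of reactive astrocytes (11 of 13 rose, median 0.99, adjusted p = 9.41e-05) and of fibroblasts and matrix (12 of 17 rose and 2 fell, median 1.28, adjusted p = 0.000128) moved with them, each with an adjusted p = 0.485 with an estimated correlation. Examples are Serpina3n (1.64, SE 0.146), Cd44 (1.15, SE 0.152), Vim (0.99, SE 0.117), Tnc (1.94, SE 0.146) and Col1a1 (1.78, SE 0.148). Thy1 (1.17, SE 0.0599), of the fibroblast list, is also a surface gene of neurons. It already stood at 5399 (SD 167) in control cultures, so its rise does not speak for fibroblasts. Among the largest rises were vitronectin (Vtn, 3.58, SE 0.200, adjusted p = 2.08e-06), Itih5 (3.06, SE 0.296), the retinoic acid enzyme Aldh1a2 (3.00, SE 0.460), Necab3 (2.79, SE 0.145), Sod3 (2.79, SE 0.253) and Apod (2.77, SE 0.204).

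Glycolysis genes in Nes-KO neurons held 16 that rose and 1 that fell of 27 (median 0.23, camera adjusted p = 0.00363, adjusted p = 0.503 with an estimated correlation), and pan-neuronal markers 8 that rose and 1 that fell of 15 (median 0.21, adjusted p = 0.0107, adjusted p = 0.485 with an estimated correlation). Of 13 mitochondrially encoded transcripts 7 rose, 11 adjusted over the list alone (median 0.50, adjusted p = 0.00131, adjusted p = 0.485 with an estimated correlation), with ND1 at 0.50 (SE 0.0814). Of 7 endothelial and pericyte markers 4 rose (mean 1.15, adjusted p = 0.0174, adjusted p = 0.485 with an estimated correlation). The authors' deposited values call 5398 genes, 2766 higher and 2632 lower.

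**Figure D3:**
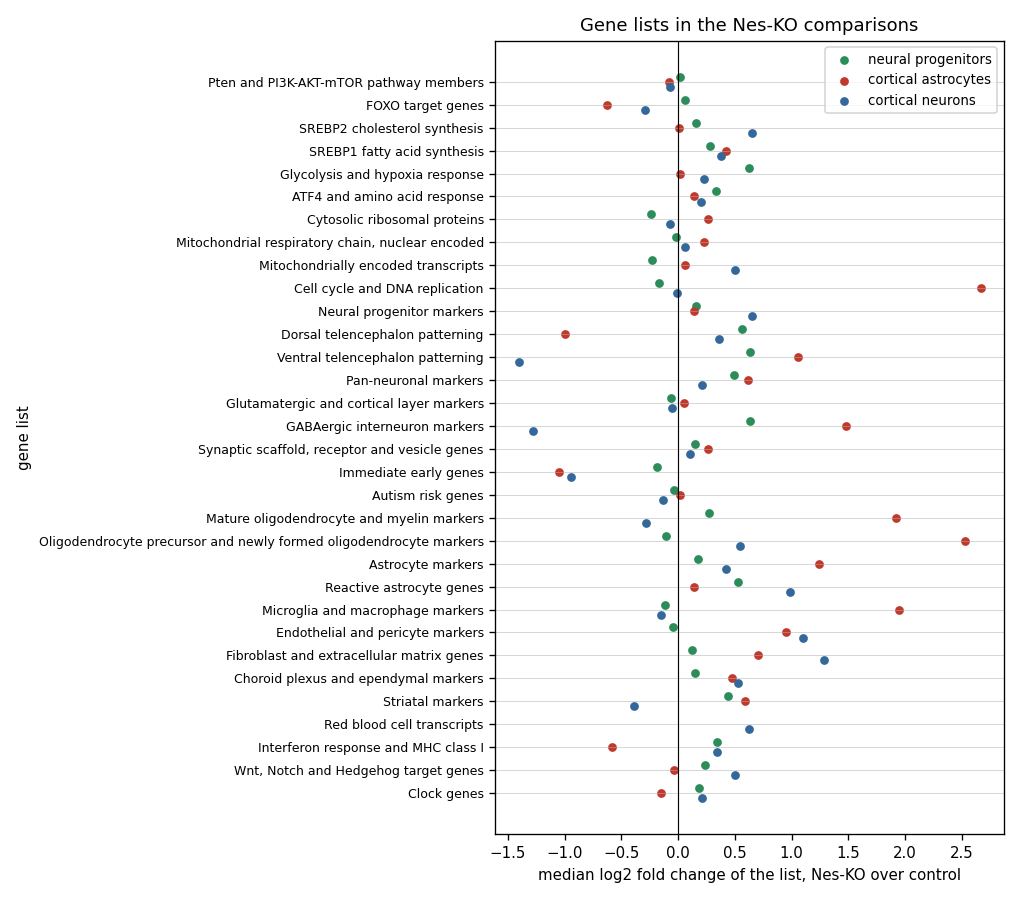
Median log2 fold change (x axis) of each gene list in the 3 Nes-KO comparisons, green for progenitors, red for astrocytes and blue for neurons. Cell cycle genes lie at 2.67 in astrocytes and -0.17 in progenitors, and interneuron markers at -1.28 in neurons.

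Whether the Nes-KO effect differs from the Pten+/- effect was tested with edgeR on both series of a cell type. The series also differ in sequencer model and, in astrocytes, in age. In astrocytes the difference holds sex as well, since every Nes-KO culture was Y-positive and no control was. In progenitors 119 genes differed, 96 higher and 23 lower, in astrocytes 6082 (3152 and 2930) and in neurons 3808 (1814 and 1994). The count in progenitors was unstable, from 22 to 999 with 1 of the 12 libraries left out, each of which moved it by over 1.5 times, and 380 with DESeq2. In progenitors the adhesion gene Parvb had a difference of 1.88 (adjusted p = 9.52e-06). The mitochondrial citrate carrier Slc25a1 (0.79), Fgfbp3 (1.45), Sez6 (0.61) and Car3 (-1.48) followed with an adjusted p = 0.00171 each. In astrocytes Wnt7b (6.86, adjusted p = 1.38e-07), Tnr (4.23), the neuropeptide receptor Adcyap1r1 (6.87) and AU020206 (2.15) were higher, and Irs1 (-2.17), Pdgfb (-2.49), Boc (-1.72) and Fam43a (-4.10) lower. In neurons the neurofilaments Nefm (2.35, adjusted p = 9.64e-08) and Nefl (1.33), Stc1 (2.56) and Wfs1 (1.48) were higher, and the axon guidance ligand Slit2 (-1.74), Mxi1 (-2.07), Gnb4 (-1.47) and Sh2d3c (-1.57) lower. Immediate early genes in neurons went the other way, with a median difference of 0.51 and 6 of 18 higher, their fall being larger in Pten+/- (adjusted p = 0.0252, adjusted p = 0.625 with an estimated correlation). Pan-neuronal markers in progenitors had a median difference of 0.66, with 2 of 14 higher and 6 adjusted over the list alone (adjusted p = 5.8e-05, adjusted p = 0.0497 with an estimated correlation).

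Shared genes were counted to ask how far systems respond alike. The test takes genes as independent, so its p values may be too small. Within Pten+/-, Pten was the only gene lower in 2 cell types, and none was called in all 3. Pten was also the only lower gene that the cortex shared with astrocytes (adjusted p = 0.0209) and with neurons (adjusted p = 0.0327). The genotype itself lowers Pten, so overlaps made of Pten alone are no evidence of a shared response. Cortex and Pten+/- astrocytes shared 4 higher genes, Abca2, Col9a3, Igfbp2 and Plod1 (chosen after their values were seen, as a short list), where 0.164 would be shared by independent lists (adjusted p = 5.24e-05). Pten+/- and Nes-KO astrocytes shared 14 higher genes against 5.96 (adjusted p = 0.00123) and 9 lower against 4.67 (adjusted p = 0.0363), while 12 of the 35 genes called in both went in opposite directions. Pten+/- and Nes-KO neurons shared 14 lower genes against 6.61 (adjusted p = 0.00409), and no gene called in both went in opposite directions.

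Across the Nes-KO cell types 120 genes were higher and 32 lower in all 3, and 1133 and 925 in exactly 2. Here too the p values take genes as independent and may be too small, and the astrocyte arms also differed in sex. Progenitors and neurons shared 377 higher genes against 211 (adjusted p = 1.19e-34) and 189 lower against 148 (adjusted p = 0.000176), and 313 of the 879 genes called in both had opposite signs. Astrocytes and neurons shared 831 higher against 603 (adjusted p = 1.23e-29) and 734 lower against 561 (adjusted p = 9.02e-19), and 1123 of 2688 had opposite signs. Progenitors and astrocytes shared 285 higher against 225 (adjusted p = 1.01e-05), but 98 lower against 140 (adjusted p = 1), and 527 of 910, the larger part, had opposite signs. Over all genes tested in both, the correlation of the fold changes was 0.112, 0.0950 and -0.00532 in the same order. Lynx1, a modulator of nicotinic receptors, rose in progenitors (0.92, SE 0.0707) and neurons (1.56, SE 0.0693), as did Parvb (1.79, SE 0.107, and 1.88, SE 0.170), with no call in astrocytes (-0.18 and 0.45). The collagen Col18a1 rose in progenitors (0.59, SE 0.0614) and neurons (2.25, SE 0.105) and fell in astrocytes (-2.88, SE 0.225). The Wnt antagonist Sfrp1 (-2.25, SE 0.146, and -1.20, SE 0.0817), the convertase Pcsk6 (-2.51, SE 0.161, and -1.98, SE 0.115) and the insulin receptor substrate Irs1 (-2.12, SE 0.108, and -0.92, SE 0.0820) fell in astrocytes and neurons, with no call in progenitors (-0.22, -0.32 and -0.22). Whether effects differ between cell types was not tested.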

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

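The tests of the delayed-response genes, of the Xist level in neurons, of the astrocyte markers and of the striatal markers were chosen only after the results were seen, and the Xist slope and the oligodendrocyte mean before.

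Immediate early genes fell in Pten+/- neurons, 14 of 18 with a median of -1.77. The sex of the cultures differed between arms. With the Xist level in the model 12 of 18 were past the threshold with a median of -1.86 (median SE 0.125). Xist was low in every Pten+/- culture but in only 1 wild type (12.8, against 15248 and 12056). The fit thus compares the Pten+/- cultures in effect with that 1 wild type. It argues against sex as the whole cause only on the strength of that library. A candidate explanation is a difference in stimulation or handling shortly before harvest. A set of 11 genes was taken as the delayed response to activity. Its median was 0.0229 (bootstrap SE 0.0748), with none past the threshold by limma. The set holds Homer1 (-0.10), Ptgs2 (0.02) and Rgs2 (0.01), which can also respond early. It thus does not cleanly separate delayed from early genes. The median lay above -0.589, a cut set as a fraction of the immediate early median after the results were seen. How far these genes must move was not measured, so the cut does not settle whether activity differed for hours. In Nes-KO neurons, where the immediate early median was -0.94, theirs was -0.526, with 4 of 11 lower and 1 higher. An effect of genotype on the activity of the cultures in the last minutes, or on the induction of these genes alone, stays open and was not tested.

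Nes-KO astrocyte cultures differed from controls in 6585 genes, and sex coincided with genotype. The Xist effect seen in Pten+/- and wild-type astrocytes had a slope of -0.0211 on the Nes-KO change over 6327 autosomal genes (from -0.0516 to 0.0109 without 1 library), where a sex effect as the cause would bring the slope to 0.5 or more, so the tables argue against it for the bulk of these genes. A lower share of astrocytes could raise the markers of every other cell type, but the astrocyte markers rose too, with a median of 1.24 and 11 higher against 1 lower. Differences in preparation, density or maturity of the cultures, and an effect of the genotype on growth and lineage, stay open and were not tested. Genes on X and Y cannot be read for genotype here.

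Microglia and myelin lists both had medians above 0 in Pten+/- cortex. More white matter in the tissue could raise both, but with the mean of the oligodendrocyte genes in the model the microglia median was 0.203, against 0.228 without it. This speaks to the microglia list alone, and more white matter stays open for the myelin list. The number of microglia markers past the adjusted threshold went from 9 to 2 and the genes called from 116 to 22. The median SE of the microglia markers went from 0.0548 to 0.0746, a larger relative change than that of their fold. Of these markers 12 of 19, against 16 without the mean, had an unadjusted p under 0.05. Why calls outside this list ended was not tested. More tissue from beside the cortex may add glial genes as well. The striatal markers stood at -0.115, on the other side of 0, which speaks to striatum alone. This mean over the 4 strata includes the P30 males, with 2 Pten+/- libraries, where these markers stood lower. How far the value rests on that stratum, and whether dissection differed between groups, was not tested. Other adjoining tissue stays open and was not tested. Higher numbers of microglia and oligodendrocytes, or more of these transcripts per cell, stay open as biological readings and were not tested apart.

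Other results stand here since a test of the difference between ages, sexes or models passed. Between ages, the genotype effect on striatal markers differed by a median of 0.18 and on fibroblast genes by -0.14. Between sexes it differed by 0.23 for striatal markers, 0.0838 for SREBP2 genes, -0.29 for immediate early genes, 0.0538 for ribosomal protein genes and -0.0942 for mitochondrially encoded transcripts. None of these 7 held with an estimated correlation. No single gene passed either interaction by limma (488 and 933 genes with unadjusted p under 0.05, edgeR 0 and 0, DESeq2 0 and 1). Each interaction contains the wild-type difference by age or sex with its sign turned. In wild types, immediate early genes stood higher and ribosomal protein genes lower in females, and striatal markers lower at P42. These are opposite in sign to the interactions. How far the wild-type libraries alone make them was not tested.

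Between the 2 models 119 genes differed in progenitors (22 to 999 with 1 library left out), 6082 in astrocytes and 3808 in neurons. In progenitors the difference was 1.88 for Parvb (1.79 in Nes-KO, -0.09 in Pten+/-), 0.61 for Sez6, 0.79 for Slc25a1, 1.45 for Fgfbp3, -1.48 for Car3, -0.71 for Lima1, -1.07 for Sv2c and -0.78 for Hs3st3b1. Glycolysis genes differed by a median of 1.14, SREBP2 genes by 0.25 and ribosomal protein genes by -0.21 (adjusted p = 0.419, 0.386 and 0.386 with an estimated correlation). Part of the glycolysis difference comes from the Pten+/- series, where this list stood below 0. Wild types spread widely there, as in Kdm3a (4500, SD 1878, against 2550, SD 204, in Pten+/-). The count of 999 was without wild type 1. In astrocytes the difference was 6.86 for Wnt7b, 4.23 for Tnr, 6.87 for Adcyap1r1 and 2.15 for AU020206. It was -2.17 for Irs1 (-2.12 in Nes-KO, 0.04 in Pten+/-), -2.49 for Pdgfb, -1.72 for Boc and -4.10 for Fam43a. Cell cycle genes differed by 2.74, ribosomal protein genes by 0.25 and FOXO targets by -0.55 (adjusted p = 0.428, 0.172 and 0.416 with an estimated correlation). In neurons it was 2.35 for Nefm (2.36 in Nes-KO, 0.02 in Pten+/-), 1.33 for Nefl, 2.56 for Stc1, 1.48 for Wfs1, -1.74 for Slit2, -2.07 for Mxi1, -1.47 for Gnb4 and -1.57 for Sh2d3c. SREBP2 genes differed by 0.78, ventral patterning genes by -1.79 and interneuron markers by -1.48 (each adjusted p = 0.523 with an estimated correlation). Groups held 2 or 3 libraries, too few for the planned test of single libraries within a group.

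Libraries were also regrouped at random. In the cortex mean 1 of 100 splits, the real one, gave as many as 116 genes, and the highest other gave 36. For age in wild types it was 1 of 100 (141, highest other 5), and for sex in wild types 1 of 100 (17, highest other 2). A share of 0.01 is the smallest that 100 splits allow, so chance is unlikely for these 3 but not excluded. The splits cannot tell age from litter or batch. For the interactions, with 0 genes, the splits decide nothing, since all 100 must give as many (highest other 6 by age and 140 by sex). A split that calls 140 genes points to a structure of the samples, and what it is was not tested. Designs of 3 against 3 have 10 splits, too few for a share under 0.05. There the real count and the highest other were 2 and 0 in P30 females (1 of 10), 0 and 1 in P42 females (10 of 10), 0 and 0 in P42 males (10 of 10) and 0 and 7 in Pten+/- progenitors (10 of 10), all by limma. They were 51 and 1 in Pten+/- astrocytes, 32 and 0 in Pten+/- neurons, 1859 and 0 in Nes-KO progenitors, 6585 and 0 in Nes-KO astrocytes and 6192 and 5 in Nes-KO neurons, each with 1 of 10. For the difference between models, 2 of 40 splits gave as many in each cell type. The highest others were 539, 6210 and 3900, in splits that left the Nes-KO arms as they are, and the highest count among splits that did not was 2, 0 and 1.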

How the results depend on the processing

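Chosen only after the data were seen were edgeR and DESeq2 on the recovered reads, TMM scaling, the Xist level as a covariate, leaving out P30 males, and limma on both tables of a cell type. TMM scaling and a pseudocount of 0.25 or 5 left the direction and side of the threshold of all 243 results for named genes in limma as they were, and edgeR did so for 241 of 243. With the Xist level 121 such results stayed as they were and 7 lost the call. Without P30 males 21 stayed and 4 lost it. With a minimum absolute log2 fold change of 0.5, 63 of 267 named gene results lost the call, by construction. Leaving out 1 library at a time kept 2087 results for named genes, ended 232 calls, added 6 and reversed 18, none of them called. Of 188 list results, 5 held with an estimated correlation and 68 with fry. With the replicate block 164 of 170 list results held, and 229 of 238 for named genes. Where a value moved and nothing else is said, the cause was not tested.

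The count of called genes moved by over 1.5 times as follows. With a minimum log2 fold change of 0.5 it was 5 in the cortex mean, 0 in P30 females by limma, 23 for age, 8 for sex, 8 in Pten+/- astrocytes, 645 in Nes-KO progenitors, 3054 in Nes-KO neurons and 2309 for the difference between models in neurons, by construction. With DESeq2 it was 296 in the cortex mean, 8 in P30 females, 6 in P42 females, 4 in P42 males, 1 for the sex interaction, 390 for age, 81 for sex, 107 in Pten+/- astrocytes, 80 in Pten+/- neurons and 380 for the difference in progenitors. With the replicate block it was 1 in P30 females, 1 in P42 females, 246 in Pten+/- astrocytes, 70 in Pten+/- neurons, 3264 in Nes-KO progenitors and 644 for the difference in progenitors. With edgeR it was 1 in P42 females, with a pseudocount of 0.25 it was 1 in P42 males, and with no filter it was 90 for age. In the cortex mean an additive model gave 183 and leaving out P30 males 187. A fit of the stratum alone gave 4 in P30 females and 29 in P42 males. With the Xist level the count was 27 in Pten+/- astrocytes and 20 in Pten+/- neurons. At unadjusted p under 0.01, Pten+/- astrocytes and neurons shared 4 lower genes. This overlap, made of Pten alone at the main threshold, no longer passed (adjusted p = 0.142).

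Leaving out 1 library gave 27 to 175 genes in the cortex mean. There the count was 68 without P30 female wild type 1 and 63 without wild type 3, 27 without P30 male Pten+/- 2 and 77 without P30 male wild type 1. It was 73 without P42 female Pten+/- 2, 175 without Pten+/- 3 and 56 without wild type 2, 63 without P42 male Pten+/- 2 or 3, 76 without wild type 1 and 68 without wild type 2. Where 1 of the 2 P30 male Pten+/- libraries was left out, the lone sample is assumed to vary like the other groups. P30 females gave 0 to 3 (0 without Pten+/- 1 or any wild type, 1 without Pten+/- 2 and 3 without Pten+/- 3). P30 males gave 0 to 9 (8 without Pten+/- 1, 9 without wild type 2). P42 females gave 0 to 5 (5 without Pten+/- 1, 1 without Pten+/- 3, 2 without wild type 1). P42 males gave 0 to 1 (1 without wild type 1), the sex interaction 0 to 2 (2 without P42 female wild type 3), and the age interaction 0 throughout. Age in wild types gave 51 to 139, with 51, 62 and 87 without P30 female 1, 2 or 3, 54 and 91 without P42 female 2 or 3, and 67 and 63 without P42 male 2 or 3. Sex in wild types gave 13 to 26, with 26 without P42 female 3.

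In cultures, Pten+/- progenitors gave 0 to 290 genes (290 without wild type 1). Pten+/- astrocytes gave 4 to 151, with 28, 19 and 4 without wild type 1, 2 or 3 and 151, 29 and 20 without Pten+/- 1, 2 or 3. Pten+/- neurons gave 20 to 55, with 55 without wild type 2 and 21 and 20 without Pten+/- 2 or 3. Nes-KO progenitors gave 690 to 2265, with 1044 and 695 without control 1 or 2 and 690 without Nes-KO 2. Nes-KO astrocytes gave 4388 to 7130, with 4388 without control 2, and Nes-KO neurons 4903 to 5915. The difference between models gave 22 to 999 in progenitors. There the count was 999, 26 and 483 without wild type 1, 2 or 3, 22, 46 and 30 without Pten+/- 1, 2 or 3, 23, 23 and 62 without control 1, 2 or 3, and 205, 36 and 28 without Nes-KO 1, 2 or 3. It gave 5043 to 7124 in astrocytes and 2923 to 3800 in neurons.

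Values that changed sign were all near 0 and not called, and without 1 library they ran across 0. Nes ran from -0.082 to 0.0185 in the cortex mean (above 0 from 0.00472 to 0.0185), from -0.288 to 0.0685 in P30 females (above 0 from 0.0243), from -0.0886 to 0.174 in P30 males (below 0 up to -0.0142), from -0.0193 to 0.239 in Pten+/- progenitors, from -0.0618 to 0.0397 in Pten+/- astrocytes (above 0 from 0.00466) and from -0.0505 to 0.0878 in Nes-KO astrocytes. With age, Uty ran from -0.0808 to 0.0135 (above 0 from 0.00306) and Eif2s3y from -0.0390 to 0.00249. Not run were the Xist covariate in Nes-KO astrocytes, where sex and genotype coincide, a replicate block for the wild-type contrasts, and splits of P30 males with 2 Pten+/- libraries. Depth limits the weakly expressed genes, where counting error is largest, and genes with a mean under 10 were not tested.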

Other observations

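The 6 genes marked below were chosen only after their values were seen, and the list tests were planned. Some Nes-KO changes ran through all 3 cell types. The nicotinic receptor subunit Chrna4 rose in progenitors (0.74), astrocytes (5.35) and neurons (0.70), the matrix cross-linking enzyme Loxl2 by 1.38, 1.29 and 1.86, the lipogenic regulator Thrsp by 1.49, 1.43 and 1.61, and the synapsin Syn2 by 0.74, 3.36 and 0.85. These 4 genes are marked as chosen in that way. In progenitors the models also differed in SREBP1 genes (median 0.33, 3 of 15 higher, adjusted p = 6.13e-06, adjusted p = 0.162 with an estimated correlation). They differed too in the ATF4 response (0.55, adjusted p = 6.12e-06, adjusted p = 0.386 with an estimated correlation) and clock genes (0.60, adjusted p = 0.000143, adjusted p = 0.386 with an estimated correlation). The ATF4 and clock lists stood below 0 in the Pten+/- series, which adds to these differences. Gfap rose by 2.76 (SE 0.491, adjusted p = 0.00382) and the ciliary factor Foxj1 by 2.57 (SE 0.320) in Nes-KO astrocytes, 2 more genes chosen after their values were seen.

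In wild-type cortex further lists differed by sex. Immediate early genes stood at a median of 0.29 in females over males, with 18 of 18 above 0 (adjusted p = 0.00298, adjusted p = 0.796 with an estimated correlation). Nuclear-encoded respiratory chain genes stood at -0.06, with 57 of 60 below 0 (adjusted p = 3.25e-06, adjusted p = 0.795 with an estimated correlation). FOXO targets stood at 0.04, with 4 of 27 higher adjusted over the list alone (adjusted p = 0.0225, adjusted p = 0.795 with an estimated correlation).

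Sex varied between culture libraries. In Pten+/- progenitors Xist stood at 34630 and 37155 in 2 libraries and at 11.9 in 1, and in their wild types at 34312 in 1 and at 22.6 and 11.1 in 2. In Nes-KO neurons it stood at 5513 in 1 library and at 1.85 and 2.24 in the others, and in their controls at 8494 and 10871 in 2 and at 2.93 in 1. The Y genes did not reach the same level in those 2 Nes-KO libraries. Ddx3y stood at 418 in the second and 1018 in the third, Eif2s3y at 449.9 and 1100, Kdm5d at 122 and 389, and Uty at 121 and 287, while the first had 0 for Ddx3y, Kdm5d and Uty and 1.12 for Eif2s3y. A count of 0 allows up to 3 reads per library. Among Nes-KO astrocyte controls, the third library had Pten at 1764, against 3787 and 3609 in the others.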
